A study of Staphylococcus sp. OJ82 with 2 samples.

How the data were processed

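RNA was sequenced from stationary cells of Staphylococcus sp. OJ82 in 1 library labelled 1% NaCl and 1 library labelled 11% NaCl. Per the labels' protocols, RNA was isolated with the RNeasy Mini kit, rRNA was depleted with the MICROBExpress kit, and single reads of 36 bp were generated on an Illumina Genome Analyzer IIx. CASAVA 1.6 is named in the submitters' processing notes, with no role given. The aligner, the counting tool, the handling of strand and the genome build are not given in the sources used here, so reads from a gene and from an antisense transcript could not be told apart. Features are placed by contig number, start and end as deposited, on 27 contigs.

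Per the file headers, the deposited tables give for each of 2909 features the count of uniquely matched reads and the count of all reads. The authors' counts are whole numbers, and the count of all reads was never below that of unique reads. The deposited RPKM equals the reads of a gene per kilobase of its length, scaled by the sum of gene reads in that library, which was checked in the 2899 features above 0 at 1% NaCl and the 2898 above 0 at 11% NaCl; the scale is therefore the reads assigned to genes, not all reads. A deposited summary sheet gives the count of total, rRNA, mRNA, intergenic and unmatched reads per library, with the same total of 17500000 reads in both; how the equal totals arose is not stated. A series workbook repeats the RPKM with the authors' annotation (product, strand, COG class and COG family symbol). Its values equal those of the per-sample tables except in 4 features, which are overlapping neighbours with exchanged values; the per-sample values were used. The column names of the workbook and the file names give other salt numbers than the labels (0 and 10 in place of 1% and 11%); columns were assigned to samples through the file listed for each sample, and the labels were followed. Annotation was used for 2768 features. The other 141 features kept their values in all counts but are not named.

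For each gene the log2 ratio of (RPKM at 11% NaCl + 1) to (RPKM at 1% NaCl + 1) was computed on the RPKM as deposited, for the 2797 genes with a mean of at least 10 RPKM over both libraries. Genes were counted at sizes of at least 2-fold and at least 4-fold. With 1 library per condition there is no replicate error, so no test and no p-value is given, and a difference between these libraries is not tested as a difference between the conditions. A 95% counting interval of each ratio was taken from the exact conditional binomial interval of the reads of a gene, scaled by the gene reads of each library and without a pseudocount; shares of reads have 95% Wilson intervals. These cover counting error only. The floor for a count of 0 was set at 3 counts. The median half-width of the counting interval was 0.13 on the log2 scale. Features with under 80% of reads matched uniquely at 1% NaCl (70 of those tested) were treated as uncertain. Features overlapping another by at least 1 read length numbered 10. No gene taken by the naming rule given below shared more than 47 bp (at most 6.88% of its length) with another feature, and other genes named were not checked for this.

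Gene lists for osmoadaptation, stress, translation, energy and central metabolism, nitrogen and amino acid metabolism, nucleotides, envelope, iron, sugar uptake, DNA repair, mobile elements, secreted enzymes, carotenoids, regulators and structural RNA were fixed before the data were examined, as patterns on the gene symbol or the product text. The only symbols in the tables are COG family symbols, so a list can hold members of a family with another function, as was the case in several lists. Examples are fatty acid synthesis (FabG), the TCA cycle (CitB) and purine synthesis (PurR). Each list was described by the number of members past 2-fold, by its median log2 ratio minus that of all tested genes, and by the percentile of its median among 10000 random lists of the same size drawn from 20 bins of mean expression. Lists with under 3 measured members are given by their members. The genes named were chosen by a rule fixed at the same time: the 12 largest rises and the 12 largest falls among genes with a mean of at least 20 RPKM and a known product, in each list the 2 largest rises and the 2 largest falls of at least 2-fold and the most abundant member, and the 5 most abundant protein-coding genes of each library. Any other gene named was chosen after its values were seen, to complete a group described. The rule took 125 genes, of which 40 were at least 2-fold higher and 60 at least 2-fold lower at 11% NaCl. Symbols in the text are the COG family symbol or the name in the product text.

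The alternatives tried were pseudocounts of 0.1 and 10, no minimum and a minimum of 50 mean RPKM, centring on the median of all genes, equal sums without structural RNA and the 20 most abundant genes, TPM, the workbook values, a minimum of 20 reads, members matched on product text only, lists without their most abundant member, and 1 value per run of adjacent members. Added after the values were seen were uniquely matched reads only, lists without members whose product names another function, and random lists made of runs of neighbouring genes. Those random runs were not matched on expression.

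The procedure was tested on simulated data: reads were drawn for the genes of the 11% against 1% NaCl comparison with 200 genes altered by known folds, and 2791 genes passed the expression minimum. All 98 genes altered 5.66-fold and all 98 altered 2.83-fold were recovered past 2-fold, 0 of 2595 unaltered genes were, and 95.9% of counting intervals held the true ratio. Of 200 random lists 2.5% fell outside the central 95%. The simulation contained counting error only.

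Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. GC content was not analysed here, because no genome sequence was used. The sheets that repeat the per-sample tables were not used here.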

Results

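Transcript abundance was measured in Staphylococcus sp. OJ82, a NaCl-tolerant bacterium isolated from fermented seafood, at 1% NaCl and at 11% NaCl. Each salt condition was represented by 1 library, made from the total RNA of stationary cells after rRNA had been removed by hybridization. Each library held 17500000 reads of 36 bp. Reads assigned to genes numbered 12182492 at 1% NaCl (69.6% of the library) and 14103402 at 11% NaCl (80.6%). The share of rRNA reads was 4.30% at 1% NaCl (95% Wilson interval 4.29 to 4.31) and 0.932% at 11% NaCl (0.927 to 0.936), and the share of reads that matched nothing was 7.44% and 2.68%. The median feature had 1050 reads at 1% NaCl and 964 at 11% NaCl. A count of 0 in a gene of 1 kb allowed up to 0.246 RPKM (reads per kilobase of gene length, scaled to the gene reads of the library) at 1% NaCl and 0.213 RPKM at 11% NaCl. With 1 library per condition no difference below has a replicate check, and all intervals and floors cover counting error only.

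The comparison asked which transcripts of OJ82 differed in abundance between low and high salt. At 11% NaCl 37 of the 57 ribosomal protein genes (25 to 49 over the scalings tried) and 8 of the 9 ATP synthase genes, which encode the enzyme that couples proton flow to ATP formation, were at least 2-fold higher, and none of either group was 2-fold lower. CspA (SOJ_16760), a small cold shock protein that binds RNA, was 5.94-fold higher and was the most abundant transcript at 11% NaCl. All 9 histidine synthesis genes (8 after centring or with a pseudocount of 10) and all 7 urease genes were at least 2-fold lower at 11% NaCl. So were 10 of the 14 genes listed for branched-chain amino acid synthesis (10 of 11 without members of another function). A run of 6 adjacent genes for a galactitol phosphotransferase system, which imports and phosphorylates the sugar alcohol, was 80.6-fold lower at 11% NaCl (median of its genes). Genes listed for uptake of compatible solutes, the small organic molecules that cells accumulate against osmotic stress, numbered 18, of which 3 have products of another function. The glycine betaine transporter SOJ_17320 was 3.57-fold higher and the other 17 genes ranged from 2.36-fold higher to 4.10-fold lower.

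**Figure D1:**
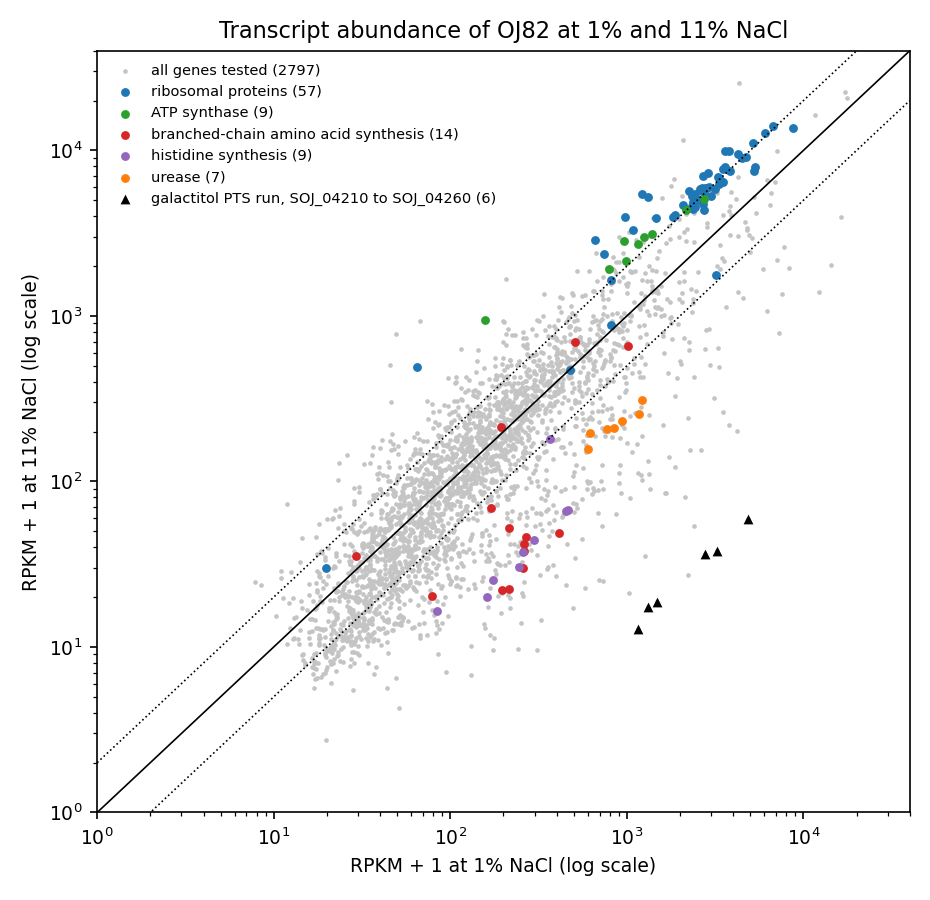
Each point is 1 of the 2797 genes tested, with RPKM + 1 at 1% NaCl on the horizontal axis and at 11% NaCl on the vertical axis, both logarithmic; the solid line marks equal values and the dotted lines 2-fold differences. Ribosomal protein and ATP synthase genes lie mostly above the diagonal, and histidine, urease and branched-chain amino acid genes and the galactitol run lie mostly below it.

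Of the 2797 genes with a mean of at least 10 RPKM, 295 were at least 2-fold higher and 682 at least 2-fold lower at 11% NaCl, and 1820 lay within 2-fold. At least 4-fold differences were found in 28 higher and 245 lower genes. Pairs of RPKM values are given at 1% NaCl and then at 11% NaCl. The median log2 ratio of all tested genes was −0.19. After centring on that median, 405 genes were at least 2-fold higher and 540 at least 2-fold lower, and at the 4-fold size 43 were higher and 206 lower. With a minimum mean of 50 RPKM the number at least 2-fold lower was 440. The 95% counting interval of all 977 genes past 2-fold excluded a ratio of 1, and that of 781 of them lay wholly beyond 2-fold.

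The highest ratios among genes with a known product began with adenylosuccinate synthetase (PurA, SOJ_02490, contig 1, 258019 to 259302), an enzyme of AMP synthesis, which went from 205 RPKM at 1% NaCl to 1672 RPKM at 11% NaCl (8.12-fold; log2 ratio 3.02, counting interval 2.98 to 3.08). Ribosomal proteins took 4 of the 12 places: L33 (SOJ_18100, 64.0 to 493 RPKM), S16 (SOJ_19120, 1211 to 5424), S18 (SOJ_01030, 663 to 2883) and a further L33 gene (SOJ_15320, 970 to 3969). ATP synthase I (SOJ_11050, contig 4, 60497 to 60847), the gene at the start of the ATP synthase run, went from 157 to 938 RPKM. CspA (contig 10, 193193 to 193393) went from 4289 to 25482 RPKM, with a log2 ratio of 2.57 (counting interval 2.54 to 2.60). The nitrite extrusion protein NarK (SOJ_08340) was 5.51-fold higher, a nitroreductase (SOJ_11750) 5.49-fold, a permease for di- and tripeptides (SOJ_23450) 4.37-fold, and a peptidyl-prolyl isomerase (SOJ_12820), a helper of protein folding, 4.02-fold. Hexulose-6-phosphate synthase (SOJ_26930) was 4.36-fold higher but is uncertain, because only 49.5% of its reads at 1% NaCl matched 1 place. Among hypothetical proteins, named here after their values were seen, SOJ_04970 (48.4 to 781 RPKM, log2 ratio 3.98), SOJ_04330 (66.2 to 929 RPKM, 3.79) and SOJ_11190 (44.4 to 505 RPKM, 3.48) had higher ratios than PurA.

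The lowest ratios were in the galactitol run on contig 2 (SOJ_04210 to SOJ_04260, 125506 to 130044). L-iditol 2-dehydrogenase (SOJ_04230), which oxidizes sugar alcohols, went from 3247 to 36.8 RPKM (log2 ratio −6.42, counting interval −6.59 to −6.34), and a zinc-binding dehydrogenase (SOJ_04210) from 4852 to 57.9 RPKM. The phosphotransferase components IIA (SOJ_04260), IIC (SOJ_04240) and IIB (SOJ_04250) had log2 ratios of −6.30, −6.25 and −6.23. A further phosphotransferase component IIB (SOJ_05840, contig 3) went from 1267 to 34.6 RPKM, and beta-glucosidase (SOJ_00950), which splits glucosides, from 239 to 8.73 RPKM. A short gene annotated as an anti peptide (SOJ_04500) went from 2393 to 52.6 RPKM. Peroxiredoxin (SOJ_01930), a peroxide-reducing enzyme, went from 309 to 8.61 RPKM, a universal stress protein (SOJ_01810) from 496.5 to 16.1 RPKM, and a lipase (SOJ_24570) from 578 to 21.6 RPKM. PdxT (SOJ_26350), the glutaminase subunit of pyridoxal phosphate synthase, went from 4201 to 199 RPKM (log2 ratio −4.39, counting interval −4.47 to −4.32).

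The most abundant protein-coding transcripts at 1% NaCl were the nucleoid protein HU (SOJ_16020, 17580 RPKM), which packs DNA, elongation factor Tu (SOJ_26060, 17087 RPKM), which brings aminoacyl-tRNA to the ribosome, a pair of ferritin-like genes (SOJ_12290, 16312 RPKM, and SOJ_28180, 14331 RPKM) and ribosome-associated protein Y (SOJ_23170, 12174 RPKM), a factor that binds idle ribosomes in stationary phase. At 11% NaCl they were CspA, elongation factor Tu (22613 RPKM), HU (20741 RPKM), elongation factor G (SOJ_26070, 16348 RPKM against 11641 RPKM at 1% NaCl) and ribosomal protein S12 (SOJ_26090, 14132 RPKM against 6719 RPKM). Ribosome-associated protein Y was 8.74-fold lower at 11% NaCl, at 1392 RPKM. The ferritin-like genes, which encode iron stores, were at 3956 and 2041 RPKM at 11% NaCl; they are uncertain because 64.0% and 47.1% of their reads at 1% NaCl matched 1 place, and on those reads alone their log2 ratios were −1.98 and −2.70. The top 10 features took 8.29% of gene reads at 1% NaCl (95% Wilson interval 8.27 to 8.30) and 10.22% at 11% NaCl (10.21 to 10.24).

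Of the 18 genes listed for compatible solute uptake, 3 were at least 2-fold higher, 1 was at least 2-fold lower and 14 lay within 2-fold. Without 3 members whose product names another function, 3 of 15 were higher and 1 was lower. The glycine betaine transporter SOJ_17320 (contig 10, 259207 to 260850) went from 670 to 2396 RPKM (log2 ratio 1.84, counting interval 1.81 to 1.87). A further glycine betaine transporter (SOJ_27390) went from 72.8 to 174 RPKM and the sodium:proline symporter (SOJ_03230) from 94.5 to 213 RPKM. The transporter of the choline, carnitine and betaine family SOJ_06500 went from 135 to 32.0 RPKM. The median of the group was 0.01 above that of all genes. Its share of gene reads, to which abundant members contribute most, was 0.301% at 1% NaCl and 0.602% at 11% NaCl. The summed RPKM of the 18 genes was 2166 and 3986, of which SOJ_17320 held 670 and 2396, so the rise rested mostly on that gene. Of the 9 genes listed for solute synthesis, 5 were at least 2-fold lower and none was 2-fold higher, with a median of −1.16 relative to all genes; the 5 were the glutamate synthase genes and their activator, among them GltB (SOJ_00090, 58.2 to 18.2 RPKM) and GltD (SOJ_00080, 53.5 to 17.2 RPKM), which make glutamate from glutamine. Of the 9, 4 have products outside solute synthesis, such as the activator and a folylpolyglutamate synthase (SOJ_14280), and without them 4 of 5 were at least 2-fold lower. Glycine betaine aldehyde dehydrogenase (SOJ_05440), which forms glycine betaine from its aldehyde, had 61.6 RPKM at 1% NaCl and 56.0 RPKM at 11% NaCl. Of the 19 genes of sodium/proton antiporters, which expel sodium ions, 16 lay within 2-fold. The exchanger SOJ_07200 was higher (44.4 to 90.2 RPKM, log2 ratio 1.01) and the NhaC antiporters SOJ_09400 and SOJ_06700 were lower (log2 ratios −1.17 and −1.01). None of the 3 was past 2-fold under every alternative: SOJ_07200 was at 0.88 to 0.998 with a pseudocount of 10, equal sums, TPM and unique reads, and after centring SOJ_09400 was at −0.98 and SOJ_06700 at −0.82. Subunit G of the multi-subunit antiporter (MnhG, SOJ_21840), the most abundant of the group, had 756 and 715 RPKM. All 4 potassium transport genes lay within 2-fold, the most abundant being TrkA (SOJ_20470), which regulates potassium uptake, with 459.9 and 533.5 RPKM.

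**Figure D2:**
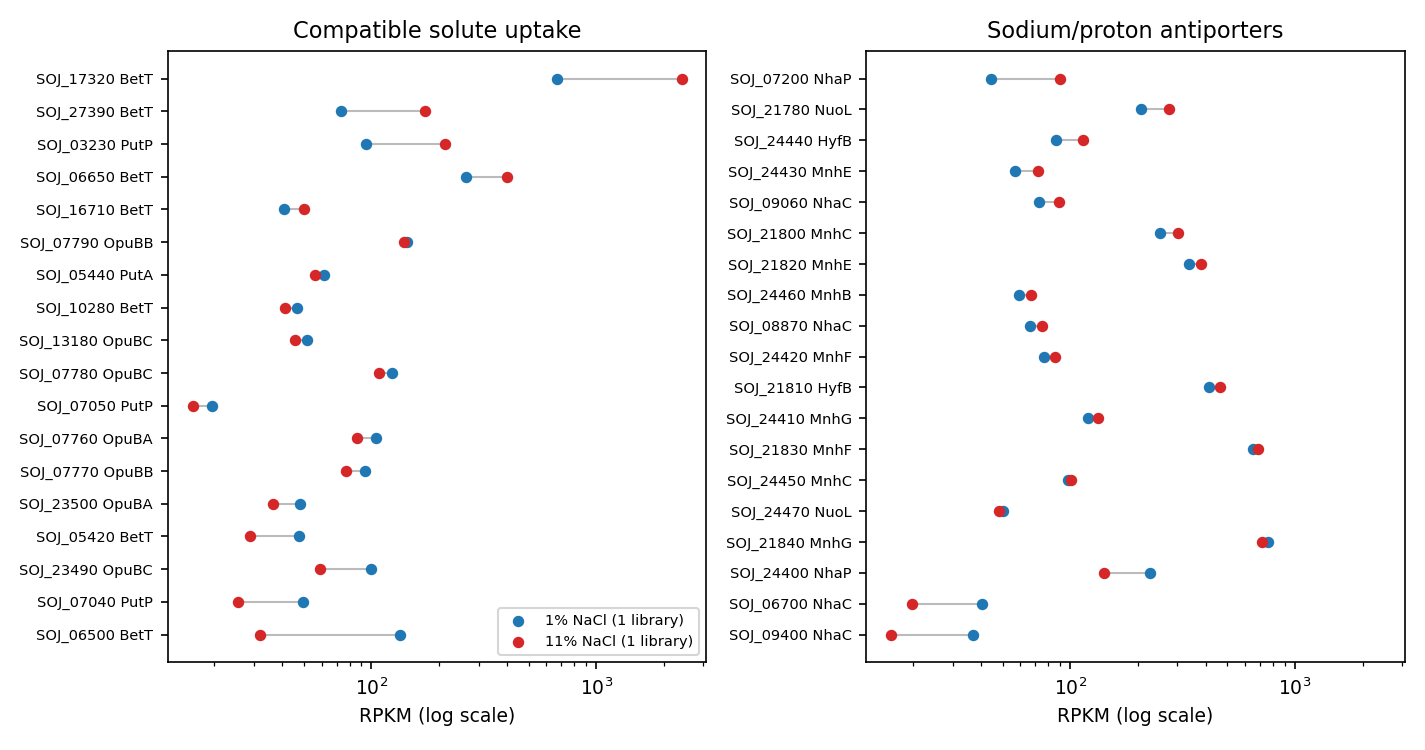
RPKM at 1% NaCl (blue) and at 11% NaCl (red), on a logarithmic axis, of the 18 genes listed for compatible solute uptake (left) and the 19 sodium/proton antiporter genes (right), 1 library per condition. The glycine betaine transporter SOJ_17320 has the largest distance to the right, from 670 to 2396 RPKM.

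Stress genes went both ways. Of the 6 genes of the general stress sigma factor SigB and alkaline shock, Asp23 (SOJ_10310), an abundant SigB-dependent protein, went from 3518 to 260.4 RPKM (13.5-fold lower), SigB itself (SOJ_11450) had 779.8 and 396 RPKM, and the L25 protein Ctc (SOJ_27930) went from 3485 to 7678 RPKM. Of the 17 chaperone and Clp protease genes 13 lay within 2-fold. ClpX (SOJ_14160), the unfolding subunit of a protease, went from 833 to 2283 RPKM and trigger factor (SOJ_14150), which folds new proteins at the ribosome, from 2056 to 5301 RPKM. A Clp ATPase (SOJ_21510) went from 2758 to 631 RPKM and CtsR (SOJ_26330), the repressor of clp genes, from 564 to 204 RPKM, and DnaK (SOJ_15040) had 4691 and 3667 RPKM. Of the 25 genes of oxidative stress defence, 2 were at least 2-fold higher (4 after centring) and 8 at least 2-fold lower. Besides peroxiredoxin, the lower ones included the catalases SOJ_01440 (683 to 87.2 RPKM, 7.75-fold lower) and SOJ_18120 (3315 to 491.5 RPKM) and the DNA-protecting protein Dps (SOJ_10750, 2927 to 828 RPKM). The higher ones were methionine sulfoxide reductase A (SOJ_04400, 91.5 to 290.2 RPKM), which repairs oxidized methionine, and a thioredoxin (SOJ_22310, 305 to 766 RPKM). Of the 4 genes listed as cold shock proteins only CspA (SOJ_16760) was past 2-fold. Of 23 DNA repair genes 4 were at least 2-fold lower and none 2-fold higher; those with the lowest ratios, an ATPase of the UvrA family annotated as a daunorubicin resistance protein (SOJ_20180) and a hydrolase of the DinB family (SOJ_04320), have products outside DNA repair.

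The median log2 ratio of the 57 ribosomal protein genes was 1.07, with quartiles of 0.91 and 1.18, close to the 2-fold size. The number at least 2-fold higher was therefore 25 with TPM and 49 after centring, against 37 as deposited, and none was 2-fold lower under any alternative. The group includes 1 gene annotated as a methyltransferase of a ribosomal protein (SOJ_15060). The group's share of gene reads was 6.78% at 1% NaCl and 13.3% at 11% NaCl. The most abundant of them, S7 (SOJ_26080), went from 8763 to 13714 RPKM, while S1 (SOJ_15990) was among the 2 with a negative log2 ratio (3185 to 1770 RPKM). Of the 20 aminoacyl-tRNA synthetases, which charge tRNA, glycyl-tRNA synthetase (SOJ_15180, 578 to 1332 RPKM) was past 2-fold (4 genes after centring), and the median lay 0.73 above that of all genes. The 9 ATP synthase genes had a median log2 ratio of 1.23, with subunit C (SOJ_11070) going from 966 to 2821 RPKM and the beta subunit (SOJ_11120) from 2729 to 5084 RPKM. In the respiratory chain 6 of 30 genes were at least 2-fold lower; the quinol oxidase genes on contig 13, the terminal oxidase that reduces oxygen, were among them (polypeptide I, SOJ_26710, 497 to 72.8 RPKM; polypeptide II, SOJ_26720, 189.7 to 30.1 RPKM, with 79.1% of reads in 1 place at 1% NaCl), whereas the more abundant set on contig 10 was not (polypeptide I, SOJ_20760, 6909 and 6435 RPKM). Of the 20 genes listed for the TCA cycle 18 lay within 2-fold (after centring 3 were at least 2-fold higher and none lower). Succinyl-CoA synthetase subunit alpha (SOJ_19030) was at 4955 and 2422 RPKM (log2 ratio −1.03, and −0.84 after centring) and a malate:quinone oxidoreductase (SOJ_08680) at 194 and 439 RPKM. Of 15 glycolysis and gluconeogenesis genes 2 were at least 2-fold lower: the glyceraldehyde phosphate dehydrogenase SOJ_14040 (1590.2 to 218 RPKM), and a phosphoglycerate mutase (SOJ_00830, 101 to 41.5 RPKM). The more abundant glyceraldehyde phosphate dehydrogenase SOJ_22940 had 4256 and 6887 RPKM. Of the 18 fermentation and acetate genes, 7 were at least 2-fold lower, among them acetyl-CoA synthetase (Acs, SOJ_13550, 1862 to 121 RPKM), which activates acetate, and AcoB of acetoin breakdown (SOJ_26450, 1357 to 89.2 RPKM). Of the 12 genes of nitrate and nitrite respiration 3 were higher and 3 lower by 2-fold (1 lower with a pseudocount of 10). Without members of another or unstated substrate 2 of 8 were higher and none lower, and with the minimum of 50 RPKM 3 of 7 were higher and none lower. NarK, the NirD-family small subunit (SOJ_08250, 107 to 399.5 RPKM) and a permease of the NarK family annotated for alpha-ketoglutarate (SOJ_02040, 54.6 to 175 RPKM) were higher, the nitrate reductase subunit NarI (SOJ_08300) had 1059.8 and 1005 RPKM, and the lower ones included a permease (SOJ_05700) and a transporter of the TauA family (SOJ_07830, 19.8 to 7.24 RPKM, log2 ratio −1.34, and −0.79 with a pseudocount of 10).

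Histidine synthesis, branched-chain amino acid synthesis and urease had the lowest list medians, each resting on a single run of adjacent genes. The 7 urease genes are 1 run (SOJ_06050 to SOJ_06110), and 8 of the 9 histidine genes are 1 run (SOJ_07460 to SOJ_07530). Among random runs of neighbouring genes urease lay at percentile 4.75, inside the central 95%, and histidine synthesis at 1.47. The 7 urease genes, which release ammonia from urea, had a median log2 ratio of −1.98; urease subunit alpha (UreC, SOJ_06090) went from 1219.8 to 309 RPKM and the accessory genes UreF (SOJ_06070) and UreG (SOJ_06060) were 4.60-fold and 4.01-fold lower. The histidine genes had a median log2 ratio of −2.78, with HisB (SOJ_07500, 244 to 29.4 RPKM) and HisC (SOJ_07510, 159 to 19.0 RPKM) the lowest and a separate aminotransferase (SOJ_23480, 365.5 to 179 RPKM) the nearest to 2-fold, with a log2 ratio of −1.02 that was −0.83 after centring and −0.99 with a pseudocount of 10. In branched-chain amino acid synthesis the median log2 ratio of the 14 listed genes was −2.29. Without 3 members whose product names another function it was −2.65, with 10 of 11 at least 2-fold lower. The acetolactate synthase subunits IlvH (SOJ_11540, 215 to 21.5 RPKM) and IlvB (SOJ_11550, 196 to 21.1 RPKM) were the lowest, in a run on contig 5, and the aminotransferase IlvE (SOJ_13380) had 1011 and 659.6 RPKM. With 1 value per run of adjacent genes that group's median was −0.048 relative to all genes, so its position rests on the run on contig 5. Of 19 tryptophan and aromatic amino acid genes 6 were at least 2-fold lower (none of 8 with the minimum of 50 RPKM), led by TrpA (SOJ_16990, 52.9 to 14.2 RPKM) and TrpE (SOJ_17050, 28.7 to 8.16 RPKM). Of 22 methionine and cysteine genes 7 were lower (1 of 11 with the minimum of 50 RPKM, where the median relative to all genes was 0.36 against −0.14), led by MetH (SOJ_01690, 61.4 to 12.2 RPKM) and MetC (SOJ_01680, 64.4 to 16.9 RPKM); the 2 that were higher, both of the CysG family (SOJ_08260, 140.2 to 533 RPKM, and SOJ_08230, 63.0 to 147 RPKM), are annotated as a uroporphyrin methyltransferase and as SirA. In the arginine pathway only ornithine transaminase (SOJ_21730, 1002 to 485 RPKM) was past 2-fold, and after centring its log2 ratio of −1.04 was −0.85. Of 22 genes listed for purine synthesis 3 were higher, PurA, GMP reductase (SOJ_18080, 104 to 304 RPKM) and adenylosuccinate lyase (SOJ_12130, 200.5 to 471 RPKM), and the 2 that were lower (SOJ_17190 and SOJ_09570) encode regulators of the PurR family; SOJ_09570 was at −0.96 with a pseudocount of 10. GMP synthase (SOJ_00620), the most abundant, had 1387 and 1431 RPKM. Of 12 pyrimidine genes uridylate kinase (SOJ_18930, 652 to 1413 RPKM) was past 2-fold; the median log2 ratio of that group was −0.03 and its mean 0.15.

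Among envelope genes, 38 matched the list for fatty acid and phospholipid synthesis, of which 5 were at least 2-fold higher and 12 at least 2-fold lower, with a median of −0.33 relative to all genes. The sign depended on members outside the pathway: the 20 genes whose product belongs to it had a median 0.70 above all genes, with 4 higher and 1 lower. Enoyl-ACP reductase FabI (SOJ_21250), which completes each round of chain elongation, went from 415 to 1298 RPKM, acyl carrier protein (SOJ_19200) from 2176 to 3327 RPKM, and the FabG-family gene SOJ_02030 from 85.1 to 264 RPKM. The lowest members were a D-alanine ligase subunit matched as AcpP (SOJ_21970, 553 to 77.5 RPKM) and a sorbitol-6-phosphate dehydrogenase matched as FabG (SOJ_02020, 95.6 to 14.3 RPKM). Of 45 peptidoglycan and teichoic acid genes 2 were higher, MurE (SOJ_12300, 105 to 267 RPKM) and the undecaprenyl pyrophosphate phosphatase BacA (SOJ_23860, 218 to 537 RPKM), and 13 were lower (9 of 40 without members of another function). The lowest were DltB (SOJ_21980, 373 to 49.0 RPKM) and DltD (SOJ_21960, 714 to 99.6 RPKM), which add D-alanine to teichoic acids, and penicillin-binding protein 2 (SOJ_16230) had 1378 and 1893 RPKM. Of the 29 sugar phosphotransferase genes 13 were at least 2-fold lower, 11 of them at least 4-fold, and none was 2-fold higher; the general carrier HPr (SOJ_20520) had 4129 and 5099 RPKM.

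Of 25 iron uptake and storage genes 6 were at least 2-fold lower (3 of 18 with the minimum of 50 RPKM), with the ferritin-like pair at the bottom, and 2 were higher, a siderophore transporter ATPase (SOJ_23350, 183 to 371 RPKM, log2 ratio 1.02, and 0.93 with TPM) and a zinc-responsive regulator of the Fur family (SOJ_15290, 58.1 to 135 RPKM). Of 54 proteases, peptidases and lipases 5 were higher and 14 lower (7 and 7 after centring, 4 and 10 with a pseudocount of 10); a carboxylesterase (SOJ_00220, 74.2 to 239 RPKM) and the membrane protease HflB (SOJ_28030, 776 to 1866 RPKM) were higher, a lysophospholipase (SOJ_22560, 215 to 16.1 RPKM) was lower, and a phosphodiesterase (SOJ_18630) had 1399.9 and 1443 RPKM. Of 24 phage and mobile element genes 8 were lower (4 after centring, 3 with a pseudocount of 10, and 1 of 7 with the minimum of 50 RPKM) and none higher, with a terminase large subunit (SOJ_17630, 32.6 to 9.20 RPKM) and a transposase (SOJ_26640, 91.0 to 35.5 RPKM, with 74.3% of reads in 1 place at 1% NaCl) the lowest and an integrase (SOJ_00600) at 292 and 171 RPKM. Among 19 agr and other sensor-regulator genes, AgrB (SOJ_11730), which processes the quorum-sensing peptide, went from 7734 to 2601 RPKM and a hypothetical protein of the LytR family (SOJ_28340) from 49.4 to 164 RPKM. Without members of another or unstated function 1 of 14 was at least 2-fold lower and none 2-fold higher. The carotenoid synthesis genes were the squalene synthase genes SOJ_03610 (71.7 and 46.4 RPKM) and SOJ_03600 (43.7 and 27.2 RPKM). Of 60 structural RNA features, most of them tRNA genes, 11 were higher (6 with TPM), such as tRNA-Cys (SOJ_t00330, 109 to 305 RPKM) and tRNA-Gly (SOJ_t00370, 267 to 736 RPKM), and 4 lower; the lowest, a tRNA-Leu (SOJ_t00550) and a tRNA-Glu (SOJ_t00450), and the most abundant, a tRNA-Gln (SOJ_t00080, 832 and 1610.0 RPKM), are uncertain because under 80% of their reads matched 1 place.

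**Figure D3:**
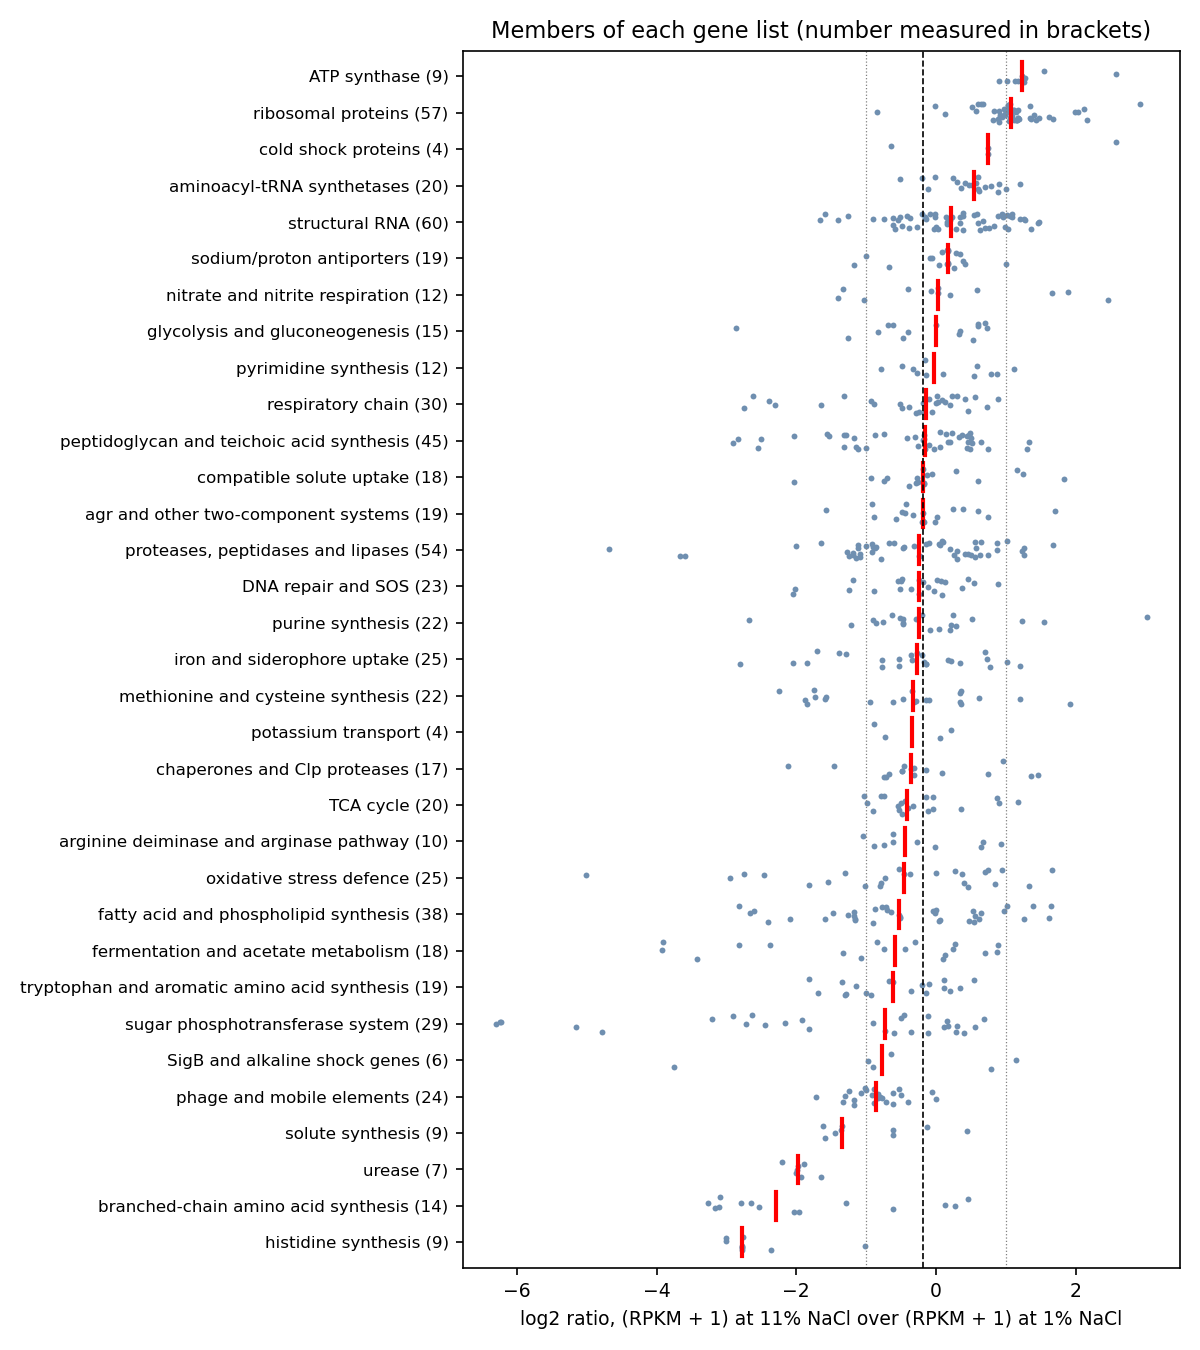
Log2 ratio of RPKM + 1 at 11% NaCl over RPKM + 1 at 1% NaCl for each measured member of each list of at least 3 genes (points), with the median of each list (red bar), the median of all tested genes (dashed line, −0.19) and 2-fold differences (dotted lines). List medians run from −2.78 in histidine synthesis to 1.23 in ATP synthase.

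As a description of these libraries, each list's median was placed among those of 10000 random lists of the same size matched on mean expression. The ribosomal protein list lay at percentile 100, ATP synthase at 99.8, aminoacyl-tRNA synthetases at 99.1 and structural RNA at 98.97. At the low end were histidine synthesis at percentile 0, branched-chain amino acid synthesis at 0.01, urease at 0.14, sugar phosphotransferase genes at 0.32, solute synthesis at 0.98, fatty acid and phospholipid synthesis as well as oxidative stress defence at 1.24, and fermentation and acetate at 2.31. These 12 lists were outside the central 95% of the random lists. Without members of another function fatty acid and phospholipid synthesis lay at the opposite end, at percentile 98.4, and solute synthesis was inside the central 95%, at percentile 2.77. Compatible solute uptake lay at percentile 62.7 and sodium/proton antiporters at 89.5. Neighbouring bacterial genes often share a transcript, so random lists were also made of runs of neighbouring genes, without matching on expression. Against these random runs 7 lists were outside the central 95%: ribosomal proteins, ATP synthase, aminoacyl-tRNA synthetases, histidine synthesis, branched-chain amino acid synthesis, solute synthesis, and phage and mobile elements. Phage and mobile elements lay at percentile 25.2 among the lists matched on expression, so only the unmatched runs set them apart. Of the 7 lists, solute synthesis was again inside without members of another function. The same step moved 2 lists outside: sugar phosphotransferase genes from percentile 4.27 to 1.68, and fatty acid and phospholipid synthesis from 7.89 to 99.2.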

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

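The uniquely matched reads, the lists without members of another function and the random runs of neighbours were chosen after the results were seen; the other alternatives were fixed beforehand. No paired analysis was possible because each condition had 1 library. Of 40 values of the gene counts under the alternatives, 38 stayed within 1.5 times the count reported; the genes at least 2-fold lower numbered 440 with a minimum mean of 50 RPKM, where fewer genes were tested, and the genes at least 4-fold higher numbered 43 after centring, which adds 0.19 to every log2 ratio. Of 457 values of the list medians relative to all genes, 444 stayed within the spread of the list's members by resampling, 11 moved further and 2 reversed. Only lists outside the central 95% of random lists were counted as reversed, and in 11 lists inside it a further 21 values, 2 of them among the 11 that moved further, had the opposite sign to the median reported. With the minimum of 50 RPKM, which takes the median of all genes from −0.19 to −0.02 and leaves out members of low abundance, the medians were 0.19 for sodium/proton antiporters, 1.09 for ribosomal proteins, −0.38 for the TCA cycle, −1.96 for urease, 0.36 for methionine and cysteine synthesis (reported as −0.14) and −0.49 for phage and mobile elements. A pseudocount of 10 gave −0.42 for phage and mobile elements, since it shrinks ratios of genes with low RPKM. With 1 value per run of adjacent members the medians were 1.34 for ribosomal proteins, −0.048 for branched-chain amino acid synthesis and 0.092 for tryptophan and aromatic amino acid synthesis (reported as −0.42), since each long run then counts once. Fatty acid and phospholipid synthesis reversed to 0.73 when matched on product text and to 0.70 without members of another function, both of which leave out FabG-family dehydrogenases. Structural RNA moved to 0.73 on uniquely matched reads; the cause was not tested. With random runs of neighbours, which were not matched on expression, 7 lists lay outside the central 95%, against 12 with random single genes matched on it. For the 125 named genes, 1004 of 1235 values stayed within the counting interval, 231 moved beyond it, none reversed, the largest move was 0.91 on the log2 scale, and 17 values of genes past 2-fold dropped under it, in SOJ_07200, SOJ_09400, SOJ_06700, SOJ_19030, SOJ_07830, SOJ_21730, SOJ_23480, SOJ_09570, SOJ_23350 and SOJ_26090. An alternative gave no value for a named gene under its minimum or a list left with under 3 values. A minimum of 20 reads removed no tested gene, so it says nothing about stability. The counting interval excluded a ratio of 1 in all 977 genes past 2-fold, which were chosen for their size. In 781 of them it lay wholly beyond 2-fold.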

Other observations

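The patterns, their tests and the counts by COG class and by run were all chosen after the results were seen. For the tests of gene length, growth genes and read depth the bounds were written before the test's own value was seen, though ratios and counting intervals of single genes were known. For the tests of library scaling and of shared reads the bounds were written after values that bear on them had been seen. The COG classes overlap the fixed lists but cover more genes. Of 147 genes in the COG class of translation 44 were at least 2-fold higher and 5 lower at 11% NaCl. In amino acid transport and metabolism 6 of 208 genes were higher and 73 lower, in carbohydrate transport and metabolism 16 of 207 were higher and 69 lower, in lipid metabolism 6 of 79 were higher and 26 lower, and in secondary metabolism 1 of 45 was higher and 22 lower. Runs of at least 4 adjacent genes held 81 of the 227 annotated genes at least 4-fold lower, in 16 runs, and 45 of the 281 annotated genes at least 2-fold higher, in 10 runs.

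The 16 runs at least 4-fold lower at 11% NaCl were not tested for a shared function. As examples chosen after their values were seen, they include fatty acid oxidation (SOJ_01760 to SOJ_01790, contig 1, 180145 to 186501, with a median 9.59-fold lower), acetoin dehydrogenase (SOJ_26440 to SOJ_26470, contig 13, 3757 to 8482, 13.4-fold), mannitol uptake (SOJ_10520 to SOJ_10550, contig 4, 8366 to 13524, 6.06-fold), ribose uptake (SOJ_17150 to SOJ_17190, contig 10, 235680 to 239545, 5.00-fold) and a peptide transporter (SOJ_21410 to SOJ_21440, contig 10, 676937 to 681712, 5.68-fold). A run with beta-glucosidase (SOJ_00940 to SOJ_00980, contig 1, 88302 to 93566) was 18.4-fold lower, and the dlt run for D-alanylation of teichoic acid (SOJ_21950 to SOJ_22000, contig 11, 22242 to 26473) was 7.30-fold lower. Polyphosphate kinase (SOJ_07570) went from 869 to 62.3 RPKM, the neighbouring exopolyphosphatase (SOJ_07580) from 452 to 22.6 RPKM, and PdxS (SOJ_26360), the partner of PdxT in pyridoxal phosphate synthesis, from 3802 to 218 RPKM. Among runs at least 2-fold higher was translation initiation factor IF-3 with ribosomal proteins L35 and L20 (SOJ_14100 to SOJ_14130, contig 8, 33418 to 35308, 3.25-fold).

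The first pattern weighed is the higher abundance of ribosomal protein genes at 11% NaCl. Their short length is argued against by the list's median at percentile 100 of 10000 lists matched on gene length. The list's median log2 ratio stayed at 0.98 or more under every scaling tried. Each of these scalings shifts all genes by nearly the same small amount. They therefore exclude neither a larger scaling error nor one that varies with abundance. A hypothesis that stays open is that the 11% NaCl culture may have been less far into stationary phase when it was sampled: 36 other growth genes (RNA polymerase, translation factors without elongation factors Tu and G, DNA replication and cell division) had a median log2 ratio of 0.38, at percentile 92.7, between the bounds written for and against it. The lists behind that percentile were drawn from all tested genes, the ribosomal protein genes included, which could lower it. Among random runs of neighbouring genes, used after the results were seen and not matched on expression, the median of the 36 genes lay at percentile 99.6. Without that match it cannot be set beside 92.7, and it does not weigh for the hypothesis. Of these genes 3 of 6 for cell division (median 0.96), 1 of 5 for RNA polymerase (0.80), 1 of 9 translation factors (0.65) and none of 16 for DNA replication (−0.14) were at least 2-fold higher. In that order the groups lay at percentiles 97.7, 75.15, 83.2 and 31.5 of matched lists, and no bounds were written for single groups. Every gene for cell division, RNA polymerase and translation factors had a positive log2 ratio, whereas those for DNA replication went both ways. Growth stage and a direct effect of salt cannot be told apart here, as growth was not measured in the tables used.

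The second pattern is that 245 genes were at least 4-fold lower but 28 at least 4-fold higher. The number lower was still 4.79 times the number higher after centring on the median of all genes, which argues against that uniform shift as the only cause at 4-fold. As for the first pattern, a small uniform shift excludes neither a larger scaling error nor one that varies with abundance. At the 2-fold size 682 genes were lower and 295 higher as deposited, but 540 and 405 after centring. Scaling may thus account for part of the imbalance at 2-fold. Of the 4-fold lower genes 100% had a counting interval that ended below a 2-fold fall, so counting error does not account for the single falls. As these genes were chosen for being 4-fold lower, that outcome was nearly given. It does not test whether read depth bears on the imbalance. With the minimum of 50 mean RPKM, which leaves out genes of low abundance, 216 genes were at least 4-fold lower and 27 at least 4-fold higher. Genes under that minimum therefore do not account for the imbalance at 4-fold. The lower abundance of these genes may reflect the condition or the stage of the culture. With 1 library per condition this hypothesis cannot be separated from a difference between single cultures.

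The third pattern is that 1 of 2 quinol oxidase gene sets was lower at 11% NaCl. Reads shared between the copies are argued against: on uniquely matched reads alone the median log2 ratio was −0.03 for the set on contig 10 (605754 to 609745) and −2.45 for the set on contig 13 (33252 to 37045), a difference of 2.42. As a hypothesis, the 2 sets may be regulated separately, with the contig 10 set, at 5244 to 6909 RPKM at 1% NaCl against 189.7 to 497 RPKM for the other, as the main oxidase in both conditions; no regulator was tested.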
